A study of Caenorhabditis elegans with 6 samples.

How the data were processed

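HAM-1 is a winged-helix DNA-binding protein of Caenorhabditis elegans that is needed for asymmetric divisions of neuroblasts. The series mapped where a HAM-1::GFP fusion protein lies on chromatin in hermaphrodites at the L4 larval stage, the last before adulthood. Per the labels, strain OP102 carries a ham-1 transgene with EGFP and other tags, and an unc-119 rescue gene. Worms were grown at 20 °C on HB101 bacteria and crosslinked with 2% formaldehyde, and 10% of the sonicated lysate was set aside as input, per the labels' protocols. The rest was precipitated with an antibody against GFP. The samples fall into a ChIP group of 3 replicates and an input group of 3 replicates, as their titles give them. The input libraries were not analysed here, so no value was compared with input beyond what the authors' region calling had already done.

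The files used were the authors' lists of binding regions, 1 for each ChIP replicate and 1 combined list. Per the file headers the coordinates are on WormBase genome build WS220, and they are given here as the files give them. Per the source column of the deposited files, regions came from SPP, a ChIP-seq peak caller, with IDR, a method that keeps regions of reproducible rank. The aligner, versions, thresholds and the way the combined list was made are not given in the sources used here. Each region has a deposited score with no stated unit. The score stops at a highest value that differs between lists and is shared by 5292 to 7157 regions of a replicate list and by 5414 regions of the combined list. Region names carry a number that runs through each list exactly once. Regions at the highest score hold the lowest numbers in every list, and across regions the number and the score had a Spearman rho of -0.99 to -1.00 in the replicate lists and -0.85 in the combined list. This number was taken as the authors' order of regions from strong to weak. The choice was made after the score was seen to be tied. The lists hold no read counts, so the sequencing depth of each library is unknown. Intervals given for shares of regions cover counting error only, and neighbouring regions are not independent. Nothing in the labels says that replicates came from separate cultures, so spread between replicates may be technical.

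All analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and overlaps were counted with bedtools 2.31.1. Regions counted as shared where they had at least 1 bp in common. Mitochondrial regions were left out of all comparisons in the report. The highest end coordinate in any list stood for the length of each chromosome, which gave a nuclear span of 100.2 Mb. Overlap and density were tested against 1000 random shifts of a list along the joined chromosomes, which keep the spacing and width of regions. Each chromosome was split into 3 equal parts for the comparison of centre and outer parts. Shifts were also planned and run for the recovery of the combined list in the replicate lists, but these lists come from the same libraries, which fixes the outcome, and no p is given for it. The shift tests were two-sided, with a smallest p of 0.002. The closing section also uses one-sided and two-sided permutation tests of 100000 permutations, or 10000 where the choice of length and chromosome is allowed for, each named there, and these can give smaller p. For the shift tests, Benjamini-Hochberg adjustment was made over the 3 pairs of replicates and over the 14 comparisons of density. The comparison of autosomes with X for the centre of chromosomes was added after the data were seen; the other comparisons had been fixed in advance. Order was compared by Spearman's rho across regions matched one to one, the strongest overlapping region being taken on both sides.

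The code was tested on simulated lists. In lists planted with 59.8% shared regions, 70.6% met a region of the partner, where unrelated regions met one in 22.7% of cases. The shift test called 4 of 100 unrelated pairs at p under 0.05. At an unadjusted p under 0.05, the density test called chromosome X in 4 of 100 lists of even density and in 19 of 20 lists with 1.5 times the density on X. The simulated lists held small clusters but no broad dense and sparse parts. These counts therefore do not give the power of the adjusted density tests on the real lists. Unrelated lists were also drawn independently of each other. Their count does not show how often the shift test would call lists that share dense parts without sharing sites.

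The rule for named regions, fixed before the data were examined, took the 10 strongest of the combined list, with a summary of the 25 strongest, by the score with ties by position. Because 5414 combined regions share the highest score, that ranking would have gone by position alone, and the authors' order was put in its place after the data were seen. The same rule would have named genes with a transcript start within a set window, and ham-1, unc-119 and pig-1. The gene table at hand is on WBcel235, another build than WS220, and no genome sequence was used. Positions relative to genes, the 27 gene lists written beforehand, sequence motifs and the 2 loci carried by the transgene were therefore not tested, and no gene is assigned to a region. Alternatives tried were other definitions of shared regions, shorter lists, merged regions, a wider chromosome centre, covered length, stretches shared by the 3 replicate lists, shorter shifts, score in place of order, and leaving out each replicate.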

Results

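Binding of HAM-1::GFP was mapped by chromatin immunoprecipitation and sequencing in L4 hermaphrodites, with 3 ChIP replicates. The authors listed 30000 regions for replicate 1, 30000 for replicate 2 and 29621 for replicate 3, and 8430 regions in a combined list. Replicates 1 and 2 have the same round number, as a limit on list length would give, and agreement fell along the lists (below). The replicate counts therefore need not be numbers of reproducible binding sites. Many listed regions overlap one another. After merging, the nuclear regions of the replicate lists formed 23082 ± 298 (SD, n = 3) separate stretches, which covered 12.1% ± 0.32 (SD, n = 3) of the nuclear span. The combined list formed 7818 stretches and covered 3.24 Mb, or 3.23% of the span. The usual region was 460 bp wide in the replicate 1 list, 476 bp in replicate 2, 444 bp in replicate 3 and 460 bp in the combined list. The first 1000 places of the replicate lists held narrower regions, with median widths of 270.5, 279.5 and 269 bp in replicates 1, 2 and 3.

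The first comparison asked which sites were bound most strongly. The 10 strongest regions of the combined list lay on chromosomes X, III, IV and II, and each stood within the first 12 places of all 3 replicate lists. The combined list rests on the same replicates, so high places there are largely given by the choice of regions and are no separate evidence. The strongest was on chromosome III from 3866897 to 3867831, and it was placed 1, 8 and 3 in the lists of replicates 1, 2 and 3. The next lay on chromosome II from 10563284 to 10563736, with places 3, 3 and 2. Chromosome III held 2 more, from 10758900 to 10759416 and from 7854404 to 7854829, at combined places 3 and 8. Chromosome IV held the regions from 4749844 to 4750271 and from 654698 to 655150, at combined places 4 and 10. The other 4 were on X, from 11093723 to 11094451, 6296178 to 6296932, 9465474 to 9466132 and 14525375 to 14526295, at combined places 5, 6, 7 and 9. The 25 strongest regions comprised 12 on X, 6 on III, 3 on II, 2 on IV, 2 on I and 0 on V, and the lowest place any of them held in a replicate list was 57. They were 401 to 950 bp wide. All coordinates are on WS220, and the genes at these positions were not analysed here. The score could not rank these regions, since all 25 stood at its highest value of 4.04.

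The second comparison asked how far the replicates found the same sites. Of the nuclear regions of one replicate list, 71.2% ± 3.05 (SD, n = 3 pairs) were met by a region of another. After random shifts the mean was 21.5% ± 0.21, the SD of the 3 pair means and not the spread of single shifts. The highest single shift gave 45.4% for replicates 1 and 2, 23.02% for replicates 1 and 3 and 23.3% for replicates 2 and 3. Pairs have replicates in common and are not independent. Replicates 1 and 2 shared the most, with 74.7%. Replicates 1 and 3 shared 69.8%, and replicates 2 and 3 shared 69.1%. Each pair exceeded its shifted lists (two-sided permutation test, adjusted p = 0.002 for each, the smallest that 1000 shifts can give). Where 2 lists had the same region, its place in the authors' order was also alike, with a Spearman rho across regions of 0.73 for replicates 1 and 2 over 16829 matched regions, 0.71 for replicates 1 and 3 over 15879, and 0.71 for replicates 2 and 3 over 15524. Pearson's r of the scores was 0.70, 0.62 and 0.63 in these pairs. Regions are not independent replicates, and no p is given for these correlations.

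Agreement between replicates fell along the order. Among the first 3000 regions of a list, 98.02% ± 1.44 (SD, n = 3) were met by another replicate list and 96.9% ± 1.69 by both. From place 12001 to 15000, the share met by both was 58.3% ± 0.54 (SD, n = 3). From place 27001 onwards it was 30.5% ± 0.82, and 35.6% ± 3.62 were met by neither of the other lists. Replicate 3 had the largest share of regions of its own, 5871 or 19.8%, against 4350 or 14.5% in replicate 1 and 4587 or 15.3% in replicate 2. These shares come from single lists of different libraries, and their differences were not tested. Merged over the 3 lists there were 32230 stretches, of which 12855 or 39.9% had a region from each replicate, 6978 from 2 replicates and 12397 from 1 replicate.

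**Figure D1:**
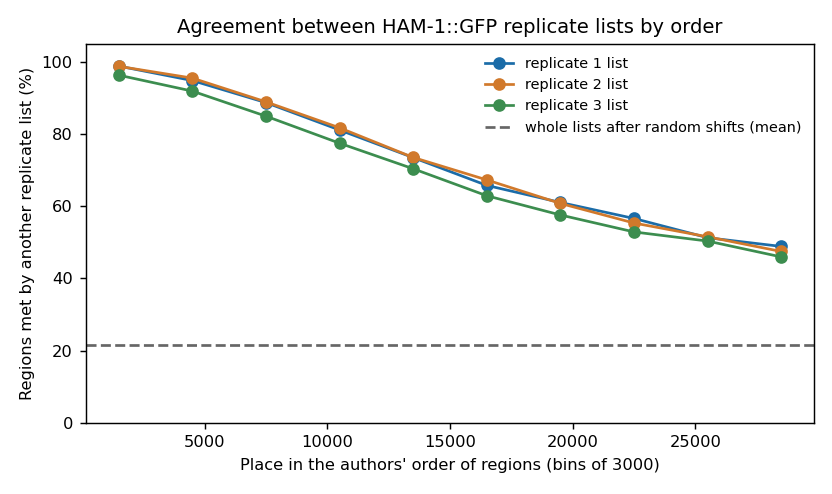
Share of regions met by another replicate list (y axis, percent, mean over the 2 other lists) against the place of the region in the authors' order (x axis, bins of 3000 regions), with 1 line for each replicate list. The share lies near 98.02% in the first bin and near 47.4% in the last, and the dashed line marks the mean of 21.5% for whole lists after random shifts.

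The third comparison asked how the combined list relates to the single libraries. It is a list of the same 3 replicates, so that high recovery in them is given by construction and was not taken as a test. All 3 replicate lists held a region at 8115 of the 8430 combined regions, or 96.3% (95% Wilson interval 95.8 to 96.6%). A further 311 regions were met by 2 replicate lists, 4 by 1 list and 0 by none, which allows a share of up to 0.0455% by the Wilson interval. The replicate 1 list met 99.4% of the combined regions, the replicate 2 list 99.1% and the replicate 3 list 97.7%. The order of the combined list followed that of replicate 1 with a rho of 0.89 across 7752 regions, that of replicate 2 with 0.88 across 7722 and that of replicate 3 with 0.82 across 7602. In the other direction, the combined list met 98.1%, 98.6% and 97.47% of the first 1000 places of replicates 1, 2 and 3, but 35.2%, 35.5% and 34.7% of their whole nuclear lists. Of the stretches with a region from each replicate, 57.8% were met by the combined list, against 3.40% of those from 2 replicates and 0.0484% of those from 1.

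The fourth comparison asked whether binding was spread evenly over the 6 nuclear chromosomes. By density in the combined list, chromosome III came first with 108 regions per Mb (1491 regions) and X next with 102.5 per Mb (1816 regions). Chromosome I had 92.9 per Mb, II 82.4 and IV 69.7, and V was last with 59.7 per Mb (1249 regions). The means of the replicate lists were also highest for III and lowest for V, with 387 ± 13.1 and 214 ± 3.04 regions per Mb (SD, n = 3), and gave 341 ± 7.90 for I, 325 ± 6.70 for X, 301.4 ± 1.08 for II and 260.3 ± 2.90 for IV. The test set each chromosome against shifted lists, which keep the spacing of regions along the genome. Shifts also keep broad dense and sparse parts, so a list shifted a short way has nearly the same ratios. That limits how small p can become, and a ratio that does not pass is no evidence of even binding. Against the other 5 chromosomes together, III was 1.35 times as dense (two-sided permutation test, p = 0.038, adjusted p = 0.27), X 1.28 times (permutation p = 0.25, adjusted p = 0.49) and V 0.66 times (permutation p = 0.11, adjusted p = 0.28). For I, II and IV the ratios were 1.12, 0.98 and 0.80, and no chromosome passed the threshold after adjustment.

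Within each autosome the combined list had more regions per Mb near the middle of the chromosome, a contrast that did not pass the adjusted threshold. With each chromosome split into 3 equal parts, the central part of the 5 autosomes held 2906 of 6614 regions, or 43.9%, which is 106 per Mb against 67.4 per Mb in the outer parts. As a ratio the contrast was widest on chromosome V at 2.03, with 90.3 per Mb in the centre and 44.5 outside it. The densities were 124 and 77.3 on I, 112.2 and 67.5 on II, 130.3 and 97.3 on III, and 83.4 and 62.8 on IV. On X the centre had 104.3 per Mb and the outer parts 101.6 per Mb. On III the ratio was 1.34 in the combined list but 1.06, 0.98 and 1.12 in the lists of replicates 1, 2 and 3, so that replicate 2 went the other way. The ratio of centre to outer parts on autosomes was 1.57 in the combined list and 1.24 ± 0.071 (SD, n = 3) in the replicate lists. It had a permutation p of 0.032 before adjustment and an adjusted p of 0.27. The ratio on X was 1.03 (permutation p = 0.98, adjusted p = 0.995), and the autosomal ratio was 1.53 times that of X (permutation p = 0.37, adjusted p = 0.59). At an unadjusted p under 0.05, 2 of the 14 density comparisons, chromosome III and the centre of autosomes, would have passed.

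**Figure D2:**
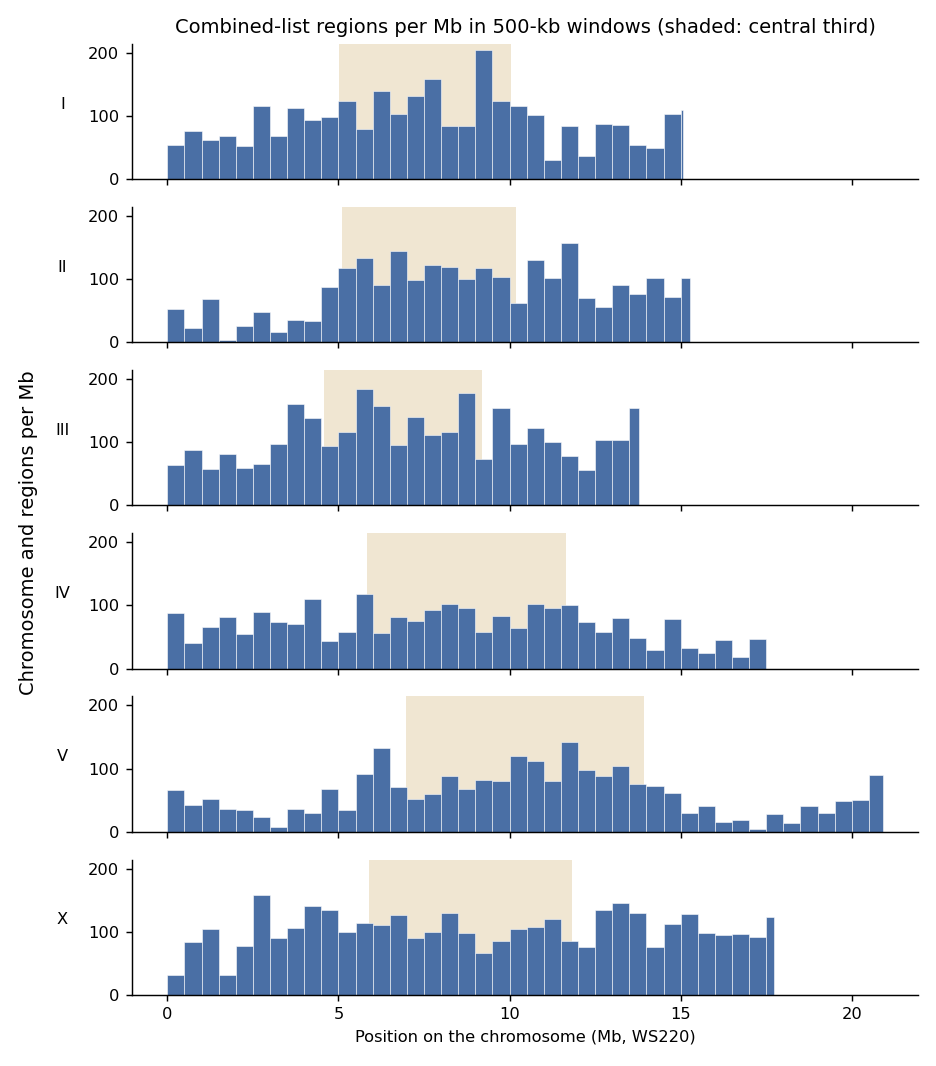
Regions of the combined list per Mb (y axis) in windows of 500 kb along each chromosome (x axis, Mb on WS220), with the central part shaded. Windows range from 4 to 204 regions per Mb, the lowest on chromosomes II and V and the highest on chromosome I between 9000001 and 9500000.

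**Figure D3:**
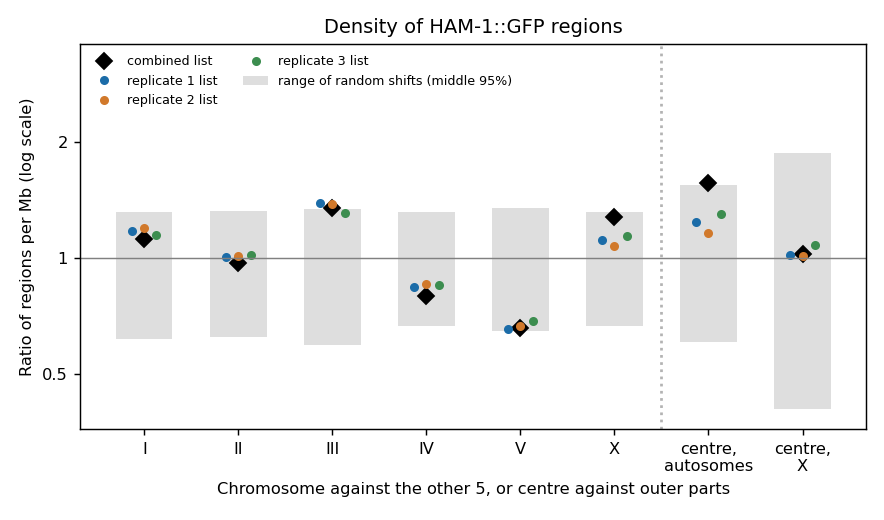
Ratio of regions per Mb (y axis, log scale) for each chromosome against the other 5 and for the centre against the outer parts, with diamonds for the combined list, points for the 3 replicate lists and grey bars for the middle 95% of 1000 random shifts of the combined list. The combined list lies slightly above the grey bar for chromosome III at 1.35 and for the centre of autosomes at 1.57, and within it for the others.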

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

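The test of coverage of mitochondrial DNA, the random placement of its regions and the rotation of lists that serves to judge the test of agreement, were chosen after the result was seen. Regions on mitochondrial DNA stand outside all comparisons of the report, and each replicate list held more of them than the 3 that a count of 0 allows: 28 in replicate 1, 20 in replicate 2 and 22 in replicate 3. The combined list held 0. The best placed of them stood at place 65 in replicate 1, 153 in replicate 2 and 5 in replicate 3, and replicate 3 had 11 within its first 1000 places against 1 in each of the others. They covered 86.4%, 45.5% and 63.6% of the mitochondrial span in replicates 1, 2 and 3, but the same regions placed at random would cover 91.2%, 40.6% and 57.9% on average, with each observed value inside the middle 95% of 1000 placements, so that coverage restates their number and width and leaves open whether the signal lay along the whole molecule or at single sites. Poor agreement between replicates as the reason for their absence from the combined list cannot be told apart from other reasons. Of the 19 mitochondrial regions within the first 8430 places of replicate 1, 89.5% were met in the same part of both other lists, above the bound of 50% that had been set to argue against poor agreement. That bound was wrong, since rotating the other lists around the molecule gave 91.9% on average, and the measure is saturated. Of the 5182 nuclear regions of replicate 1 met within the first 8430 places of both other lists, 97.45% were met by the combined list. This does not decide the question, because the mitochondrial share would be high without any agreement. Input libraries were not analysed here, and no biological explanation was tested.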

How the results depend on the processing

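Merging, shifts of 10 to 50 kb, the score and the comparison of autosomes with X were chosen after seeing the data. The overlap of replicate lists passed the permutation test under each of its 11 alternatives. Leaving out a replicate left a single pair of the main comparison, so those alternatives restate values given above and could not fail. Under the others, overlap between replicates ranged from 55.3% (200 bp around the midpoint) to 73.1% (strongest 25% of each list). Recovery of the combined list ranged from 71.3% (reciprocal overlap of 50%) to 99.2% (strongest 25% of each list). No p is given for recovery, because the combined list shares its libraries with the replicate lists. The mean rho of the order between replicates was 0.72. It moved by more than the spread between pairs under 3 alternatives, and the cause was not tested. These gave 0.69 with 50% reciprocal overlap, 0.70 in the strongest 50% of the combined list and 0.65 with the score in place of the order. With a replicate left out, rho was 0.71 to 0.73. These values are those of the single pairs given above, so they test nothing further. None of the 14 density comparisons passed the threshold under any alternative run for it, and adjusted p ranged from 0.17 to 0.999. Because shifts keep broad dense and sparse parts, which limits how small p can become, this is no evidence of even density. The ratio for the centre of X changed direction in the strongest 50% (0.995) and the strongest 25% (0.96) of the combined list, and that for chromosome II in stretches shared by all 3 replicate lists (1.04). Under these alternatives ratios were 1.34 to 1.37 for III, 1.15 to 1.31 for X, 0.60 to 0.66 for V and 1.39 to 1.67 for the centre of autosomes. The replicate lists were not among the alternatives. Their mean ratios were 1.36 for III, 1.11 for X, 0.67 for V and 1.24 for the centre of autosomes. For density, leaving out a replicate kept the combined regions met by both other lists, since the combined list itself could not be rebuilt. That kept 96.8%, 97.1% and 98.55% of them without replicates 1, 2 and 3. The density ratios could therefore hardly change, and these alternatives say little about dependence on a replicate. Alternatives for genes, gene lists, motifs and transgene loci were not run, because the gene table is on another build. No paired analysis was possible because the input libraries were not analysed here, although the labels number ChIP and input alike. Depth is unknown, so its effect on the number of weak regions could not be examined.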

Other observations

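Regions occurred in groups. In the combined list 18.7% of the gaps between merged stretches were at most 1 kb, against 10.4% with the stretches placed at random 100 times (highest 11.5%), and the median gap was 3687 bp against 8452 bp. In the replicate lists 49.5%, 47.2% and 44.5% of gaps were that short, against 29.6%, 29.5% and 29.5% at random. The random values match placement in which stretches were free to overlap, with each overlap counted as a short gap. Merged stretches do not overlap, so the random shares are too high and the random median too low for a like comparison. The direction of the contrast stands, but its size was not measured. The densest windows of 50 kb in the combined list were on chromosome II from 6800001 to 6850000 with 24 regions, on II from 10500001 to 10550000 with 23, and on V from 6200001 to 6250000 and X from 11450001 to 11500000 with 21 each, against a mean of 4.20 per window. With overlapping regions merged these held 23, 17, 19 and 17 stretches, which changes their order. Of 2008 such windows, 346 or 17.2% held none. These sites and stretches were picked after their values were seen. The longest stretch without a combined region was on chromosome II from 1520339 to 2195661, or 675 kb, where the replicate lists had 21, 27 and 23 regions, the best at places 2849, 2502 and 2986. Another on chromosome V from 15192777 to 15511655 held a site at 15464980 to 15465362 that stood at places 130, 174 and 490 in replicates 1, 2 and 3. This is 1 of 2 sites not met by the combined list among 656 regions of replicate 1 that stand within the first 1000 places of all 3 replicate lists (0.305%, 95% Wilson interval 0.0836 to 1.10%). The other is on II from 10303759 to 10303969, at places 808, 804 and 566.

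The tests of chance order for X and V, the test of median width and the tests within width classes in the replicate lists were chosen after the result was seen. X held 69 of the 250 strongest combined regions, or 27.6%, against 21.5% of all combined regions, but 22.6% of the first 1000, 22.4% of the first 2000 and 20.9% of the first 4000, so that of the 4 lengths examined the excess was largest in the shortest, small in the next 2 and absent in the longest. Chromosome V departed further, with 20 of the first 250 or 8.0%, against 14.8% of all. A chance order of regions cannot be told apart from other explanations for X in the combined list: the one-sided permutation p of 0.0127 takes no account of the choice of length and chromosome, and allowing for both gave a two-sided permutation p of 0.29 for X and 0.045 for V. In the first 8430 places of the replicate lists, where X held 73 of the first 250 nuclear regions each, the same test gave 0.038, 0.031 and 0.021 for X and 0.067, 0.10 and 0.14 for V in replicates 1, 2 and 3 (permutation p), and these tests treat regions as independent. The replicate lists also share most of their strongest regions, so their p-values are not separate pieces of evidence. Sites on X listed several times as overlapping regions are argued against, since after merging the X share of the first 250 stayed 7.14 percentage points above that of all stretches. Neighbouring regions that do not overlap were not merged, so a site split into such regions is not covered. The merged order was not tested with allowance for the choice of length and chromosome, so chance order stays open there too. Wider regions on X among the strongest may account for part. Among the 250 strongest, the median width was 502 bp on X and 423 bp on autosomes (two-sided permutation p = 0.0010). Over all combined regions the median was 460 bp on both, but 64.1% of them had exactly that width, so it could hardly differ. The lower quartile over all combined regions was 378 bp on X and 332 bp on autosomes, and the upper quartile 460 bp on both. With the order permuted within 5 width classes (10 were intended, but tied widths merged them), 59.2 X regions were expected instead of 53.9 (one-sided permutation p = 0.062). That p is above the 0.05 set beforehand as the bound for width as the cause, but the replicate lists divide on it (permutation p = 0.027, 0.066 and 0.012 in replicates 1, 2 and 3), which keeps it open, and no biological explanation was tested.

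Replicate 3 had 13 nuclear regions within its first 1000 places that no region of replicates 1 or 2 met, the best at place 228 on chromosome II from 221241 to 221365, while replicates 1 and 2 had none so strong (best places 1636 and 2019). The combined list met 1 of the 13. Region bounds moved between libraries are argued against for most of them, since the median distance to the nearest region of another replicate was 1796 bp and 8 of the 13 lay at least 1000 bp away, though 2 lay within 500 bp. The length limit of the other lists is argued against only indirectly: 0 of the 989 nuclear regions within the first 1000 places of replicate 3 had their best match after place 20000 of the other lists, and 974 had it within the first 5000. The 13 have no match by selection, so these counts come from other regions and cannot show where the 13 would have stood. What sets these 13 regions apart stays open, and no biological explanation was tested.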
